A study of Mus musculus with 8 samples.

How the data were processed

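RNA was measured in 8 libraries of mouse oligodendrocyte progenitor cells, the dividing precursors of the myelinating cells of the brain. Per the labels' protocols, the cells were immunopanned with an antibody to PDGFRα from the cortex of C57BL/6 pups at postnatal day 6 to 8, after lectin-coated dishes had removed microglia and endothelial cells. The cultures were expanded with 10 ng/mL PDGF-AA and 20 ng/mL bFGF, and PDGF-AA alone was kept during the experiment. High glucose (HG) cultures stayed at 25 mM glucose. Low glucose (LG) cultures were stepped down by medium exchange to 12.5 mM on day 1, 5 mM on day 2 and 2.5 mM on day 3, and both were harvested on day 5. Libraries were made from 100 ng of total RNA with an mRNA kit and sequenced as paired-end reads of 150 bp. Each group holds 4 libraries, which the labels describe as independent biological preparations. Numbers 1 and 2 share a preparation code in both groups, which goes against that description, so n = 4 counts libraries and not preparations.

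The deposited table holds raw counts per Ensembl gene, whole numbers that the authors had not normalized. CASAVA 1.8.2, STAR, featureCounts, DESeq2 and the build mm10 are named per the submitters' processing notes, with no role or order. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. The table lists 56980 gene IDs, of which 52073 had a symbol in the GENCODE M21 annotation of GRCm38 used here and 4907 had none, so the deposited IDs come from another release. Total counts per library ran from 50864130 to 65733928. All 37 mitochondrial gene IDs are listed at 0 in the 8 libraries, so the list of mitochondrially encoded genes could not be tested.

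Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 18905, libraries were scaled by TMM, and LG was compared with HG by the quasi-likelihood test with robust dispersion estimates. The p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. An SE given with a log2 fold change is its absolute value divided by the square root of the F statistic of that test. The test without a block was fixed as the main one before the data were examined, as were the 40 gene lists, the rule for named genes and most of the alternatives. Lists with at least 3 tested members, 39 in all, were tested by camera from limma 3.58.1 with a preset correlation of 0.01 between genes, and beside it with an estimated correlation and by fry. CPM values are normalised with the TMM factors, and log2 values for scores used a prior count of 2. The CPM levels that rank the markers of cell types use the total counts without these factors. Library measures were compared by two-sided exact permutation over 70 assignments.

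The titles number the libraries 1 to 4 in each group. The descriptions carry a preparation code that numbers 1 and 2 share, and numbers 3 and 4 have a code each, the same in both groups. Pairs 1 and 2 may therefore not be independent, while SDs and counts over 4 pairs treat them as separate. Deviations from the group means correlated between same-numbered HG and LG libraries at r from 0.448 to 0.625 across genes, which are not independent replicates, and each of the 8 libraries correlated best with its own number. The highest r between different numbers was 0.419. Y-linked genes were at 0 in both libraries numbered 3 and in no others. The numbers were therefore taken to pair the libraries, before calls were compared between fits, and the fit with the replicate block is given wherever it changes a call. In that fit 79 genes passed, against 0 without it.

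Chi-square per degree of freedom between replicates of a group was at least 19.0, so no library repeats another of its own group. A smooth trend of log2 counts on GC content and transcript length was removed per library with mgcv 1.9.3 and entered as offsets. GC content and length were known for 97.5% of the tested genes. DESeq2 1.42.0, limma-voom, other filters and scaling, stricter thresholds, thinned counts and left-out libraries or preparations were the other alternatives. Unprocessed and processed pseudogene transcripts were matched to mitochondrial transcripts with blastn 2.17.0 at 99% identity over 90% of their length. Fisher's exact test of the overlap of calls with the cell cycle lists was chosen after the calls were seen.

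The scripts' tests were tried on simulated counts for 18905 genes in the LG against HG design. The counts were drawn from means fitted to the replicate numbers without a group term, with the dispersions of the fit with the block. Differences between numbers were thus built in, so a gain with the block does not show that it suits the real data. Only genes above a set mean abundance were changed. Of 50 genes changed by 1.4-fold, edgeR recovered 22% without the block and 86% with it. For 1.8-fold changes these shares were 82% and 100%. Unchanged genes gave 0 false calls without the block and 14 with it.

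The named genes are those with the largest changes among calls (up to 8 higher and 8 lower, mean CPM of at least 5, same direction in the 4 pairs), up to 4 members of each list with the smallest p, and 12 genes fixed by name. The first part took no gene in the test without the block, so it was applied to the fit with the block, a step chosen after the values were seen. The text names 59 of the genes the rule takes, picked after their values were seen, and 2 of those fixed by name are not reported here. Figures were drawn with matplotlib 3.10.9.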

Results

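The transcriptome of oligodendrocyte progenitors was compared between cultures kept at 25 mM glucose (HG) and cultures lowered to 2.5 mM (LG), with 4 libraries in each group. Total counts per library ran from 50864130 to 61915909 in HG and from 53869166 to 65733928 in LG, and the group means did not differ by more than the spread (exact permutation test, two-sided, p = 0.543). The first principal component held 47.1% of the variance and parted libraries 1 and 2 from libraries 3 and 4 of both groups, not HG from LG.

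**Figure D1:**
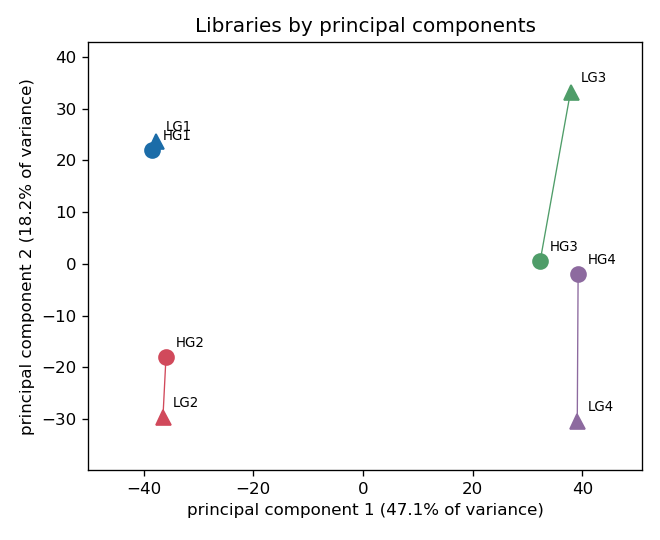
Principal components 1 (horizontal, 47.1% of variance) and 2 (vertical, 18.2%) of the 8 libraries, with circles for HG, triangles for LG, and lines that join libraries of the same number. The numbers 1 and 2 lie on the left and 3 and 4 on the right in both groups.

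No gene passed in LG against HG by edgeR's quasi-likelihood test without a block, where the smallest Benjamini-Hochberg adjusted p was 0.9999 and 745 of 18905 genes had an unadjusted p under 0.05. DESeq2 called 4 genes and limma-voom 0 in the same design. With the replicate number as a block, 79 genes passed, 21 higher and 58 lower in LG. With GC and length offsets as well, 293 passed, 87 higher and 206 lower, and 72 of the 79 were among them. The offsets without the block gave 0 genes. The changes were small: the median absolute log2 fold change of the 79 was 0.42 and the largest was 0.88. The count with the block was 0 without pair 2, 6 without pair 1, 39 without pair 3 and 148 without pair 4, and 1 with the preparation code as the block in place of the number.

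Cell cycle genes had lower counts in LG. All 42 members of the S phase list (G1/S transition and DNA replication) and all 38 of the G2/M list had negative log2 fold changes, with medians of -0.25 and -0.18 without the block. Both lists passed by camera on the edgeR fit (Benjamini-Hochberg adjusted p = 2.0e-20 and 1.4e-13), and neither passed with an estimated correlation, at adjusted p = 0.474 for S phase and adjusted p = 0.203 for G2/M. With the block these were adjusted p = 0.212 for both, while fry gave adjusted p = 0.0440 and 0.0444. With the block, 5 S phase and 5 G2/M members passed among all genes, and 32 and 23 passed adjusted over the list alone. Without it, 0 members of either list passed, also adjusted over the list alone. With the block and the offsets, 21 and 10 passed among all genes.

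Mki67, the proliferation marker Ki-67, fell in the fit with the block by 0.78 on the log2 scale (SE 0.084, edgeR adjusted p = 0.00777), from 514 ± 262 CPM in HG to 288 ± 97.1 CPM in LG (SD, n = 4). HG replicate 1 was at 901 CPM and the other HG libraries at 334 to 441 CPM, and the log2 fold change without the block ran from -0.41 without HG replicate 1 to -1.08 without LG replicate 1. The kinetochore genes Cenpe (log2 fold change -0.79) and Knl1 (-0.68), the mitotic kinesin gene Kif20b (-0.69) and the replication checkpoint genes Clspn (-0.50) and Dtl (-0.46) also fell, and each was lower in LG in 4 of 4 pairs. For Cenpe, Knl1 and Kif20b the naming rule required the same direction in the 4 pairs. Cenpf (-0.80, edgeR adjusted p = 0.0579) and Kif11 (-0.34, 0.0523) did not pass with the block alone and passed with the block and the offsets. Uhrf1 was at -0.23, Slbp at -0.25, Ccna2 at -0.16 and Gtse1 at -0.23, and none of these passed with the block alone. Of the 58 genes that fell, 10 were in the 80 members of both lists, against 0.245 expected (Fisher's exact test, p = 4.6e-14). That test treats genes as independent and was chosen after the calls were seen, so its p does not measure reproducibility over cultures. Mki67 (ENSMUSG00000031004) lies on GRCm38 chromosome 7 at 135689784 to 135716361 and Neu4 (ENSMUSG00000034000) on chromosome 1 at 94020451 to 94028334.

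**Figure D2:**
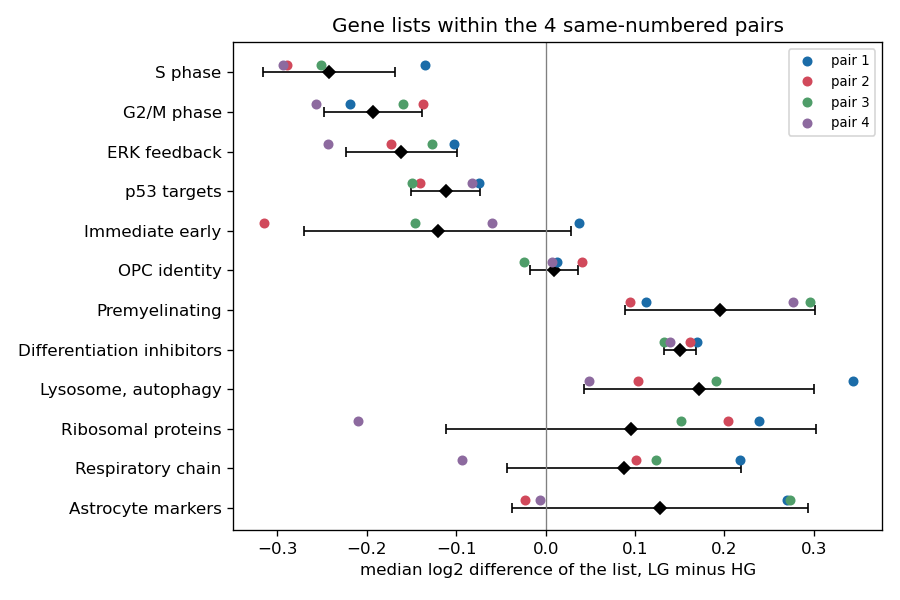
Median log2 difference, LG minus HG, of 12 gene lists (horizontal axis) in each of the 4 same-numbered pairs (coloured points), with the mean and SD over the pairs (black diamonds and bars). The S phase and G2/M lists lie below 0 in 4 of 4 pairs, while immediate early genes, progenitor identity, ribosomal proteins, the respiratory chain and astrocyte markers take both signs.

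Feedback genes of the ERK pathway, which PDGF signalling induces, were lower in LG. Of 13 tested members 12 had negative log2 fold changes, with a median of -0.17, and the list passed by camera on the edgeR fit (adjusted p = 2.7e-06), but had adjusted p = 0.168 with an estimated correlation. Spry4, a Sprouty family inhibitor, fell by 0.39 with the block (SE 0.062, edgeR adjusted p = 0.0353). Dusp6, an ERK phosphatase, was at -0.30 and Ccnd1, which encodes cyclin D1, at -0.31, and both passed with the block and the offsets. Spry2 was at -0.19. With the block 1 member passed among all genes and 6 adjusted over the list alone, against 0 and 3 without the block. The p53 target list also passed by camera (14 of 18 lower, adjusted p = 0.00136), with adjusted p = 0.168 with an estimated correlation. By fry it had adjusted p = 0.204 without the block, 0.0440 with it and 0.0575 with the block and the offsets. Its members Pmaip1 and Mdm2 were at -0.33 and -0.25, and 0 members passed among all genes with the block, 5 adjusted over the list alone and 0 without the block. With the block and the offsets, 2 p53 targets passed as lower among all genes and 6 adjusted over the list alone. Immediate early genes had 13 of 15 members lower (camera on the edgeR fit, adjusted p = 0.0367) and adjusted p = 0.469 with an estimated correlation, and the call ended without 5 of the 8 libraries left out singly (highest adjusted p = 0.241 by camera on the edgeR fit), without the preparation of numbers 1 and 2 (0.0960) or of number 3 (0.113) and with no filter (0.0616). No member passed among all genes with or without the block. Adjusted over the list alone, 2 passed with the block and 0 without it. With the offsets and the block, 1 member passed as lower among all genes and 6 adjusted over the list alone. The list difference was 0.038 in pair 1 and below 0 in the other pairs. Egr1 was at -0.32.

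Markers of committed, premyelinating oligodendrocytes were higher in LG, with 15 of 16 members positive, a median of 0.22 and adjusted p = 6.5e-05 by camera on the edgeR fit, but adjusted p = 0.168 with an estimated correlation. Neu4, a sialidase gene, rose with the block by 0.76 (SE 0.078, edgeR adjusted p = 0.00576), from 10.7 ± 4.79 CPM to 18.0 ± 7.85 CPM (SD, n = 4). It was the 1 member that passed among all genes with the block, where 9 passed adjusted over the list alone and 0 without the block. The list score of HG replicate 3 was -0.44, against -0.07 to -0.03 in the other HG libraries, and that of LG replicate 4 was 0.37, against 0.06 to 0.09 in the other LG libraries, and the list had adjusted p = 0.00800 and 0.0143 by camera on the edgeR fit without each of them. Sirt2 was at 0.30, Itpr2 at 0.20 (0.095 to 0.30 over the 25 settings) and Mpzl1 at 0.20 (0.083 to 0.32). Myrf, the transcription factor that drives myelin genes, rose by 0.60 (SE 0.067, adjusted p = 0.00871 by edgeR), and so did Fa2h (0.52, adjusted p = 0.0346 by edgeR, not passed at 0.0633 with blocked sums per preparation), which makes hydroxylated myelin lipids. Without LG replicate 4 and without HG replicate 4, in fits without the block, Neu4 was at 0.42 and 1.08 and Myrf at 0.30 and 0.90. Myelin genes as a list had 14 of 30 members higher without the block and did not pass there. With the block 16 were higher and the list passed by camera (adjusted p = 0.0349 by edgeR and limma), with adjusted p = 0.561 with an estimated correlation. It did not pass with the preparation block (0.0567) or with the offsets and the replicate block (0.0945), by camera on the edgeR fit. Mbp, at 62.7 ± 40.9 CPM in HG and 63.3 ± 31.5 CPM in LG, did not pass.

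The progenitor markers did not pass as a list in either fit (adjusted p = 0.890 by camera without the block and 0.761 with it). Pdgfra was at -0.09 and Cspg4 at 0.06 with the block. Sox8 rose by 0.37 with the block (adjusted p = 0.0381 by edgeR) and did not pass with blocked sums per preparation (0.0936). C1ql1 was at 0.42 and Vcan at -0.21, or -0.065 with the offsets as well. Genes that hold back differentiation had 12 of 16 members positive with the block and passed by camera there (adjusted p = 4.9e-05 by limma and edgeR), with adjusted p = 0.521 with an estimated correlation. Without the block they did not pass (adjusted p = 0.0557). Id3 rose by 0.46 (adjusted p = 0.0346 by edgeR; 0.0671 with blocked sums per preparation, where it did not pass), and Hes5 and Hey1 were at 0.33 and 0.28. The cell cycle inhibitor gene Cdkn1c rose by 0.55 (adjusted p = 0.0346 by edgeR, and 0.0808 with blocked sums per preparation, where it did not pass), while Cdkn1a was at -0.17. Over the 25 settings Cdkn1c passed as higher in 3 and Cdkn1a as lower in 1.

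**Figure D3:**
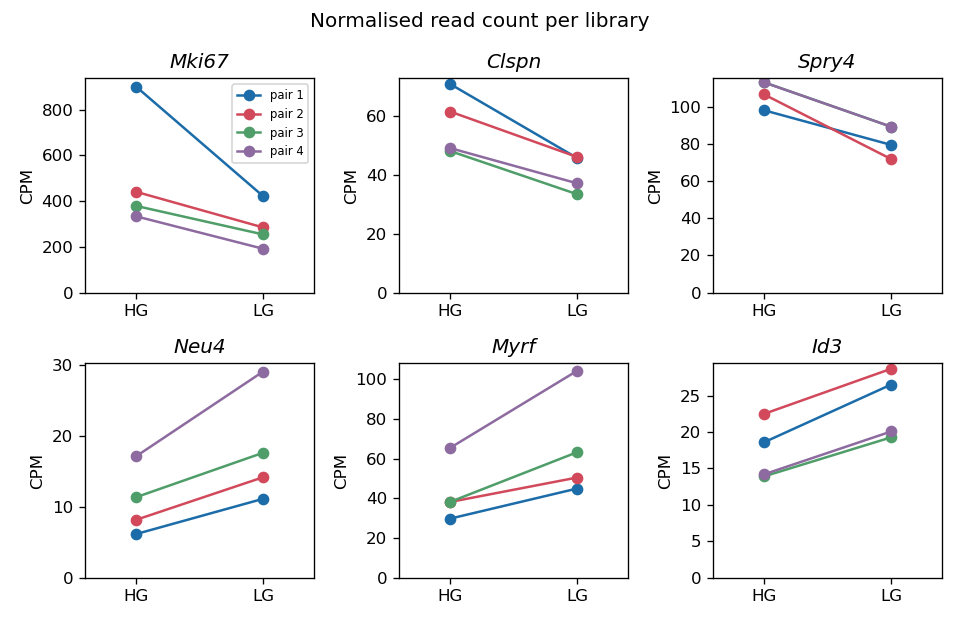
Normalised read count (CPM, vertical axis from 0) of Mki67, Clspn, Spry4, Neu4, Myrf and Id3 in the HG and LG libraries (points), joined within each same-numbered pair. Each gene moves in 1 direction in 4 of 4 pairs, and Mki67 runs from 901 CPM in HG replicate 1 to 191 CPM in LG replicate 4. The rule for genes named by the size of their change required this, and the genes were picked after their values were seen. The shared direction is therefore no separate evidence.

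No member of the glycolysis, TCA cycle, respiratory chain or fatty acid oxidation lists passed among all genes or adjusted over the list alone, with or without the block. As lists these passed upward by camera on the edgeR fit, with adjusted p = 0.0358, 0.0233, 2.1e-05 and 0.0186, and each had adjusted p = 0.577 with an estimated correlation. Glycolysis did not pass with the offsets (adjusted p = 0.589 by camera on the edgeR fit without the block and 0.394 with it), where its median with the block went from 0.08 to 0.03, and fatty acid oxidation did not pass with the offsets and the block (0.0514). Without the preparation of numbers 1 and 2 none of the 4 lists passed (lowest adjusted p = 0.549 by camera on the edgeR fit), and without that of number 3 glycolysis (0.138), the TCA cycle (0.114) and fatty acid oxidation (0.114) did not. Leaving out 1 library ended the call in 4 of 8 cases for glycolysis, 5 for the TCA cycle, 4 for fatty acid oxidation and 0 for the respiratory chain. Their medians lay between 0.07 and 0.10, and the pair 4 difference had the opposite sign for each, -0.13 for glycolysis, -0.07 for the TCA cycle, -0.09 for the respiratory chain and -0.06 for fatty acid oxidation. Pfkm was at 0.17, Hk1 at 0.11 and Gapdh at 0.12 with the block. Acly and Acss2, the enzymes that make acetyl-CoA from citrate and from acetate, were at 0.00 and 0.03, and the glucose transporter gene Slc2a1 at 0.02. Txnip, which glucose induces, was at -0.41 with 4.92 ± 0.414 CPM in HG and 3.76 ± 0.727 CPM in LG (SD, n = 4) and did not pass among all genes. Klf10 was at -0.32 with the block and passed with the offsets as well (edgeR adjusted p = 0.0301). Klf10 and Txnip were the 2 of 8 tested glucose-responsive members that passed adjusted over the list alone with the block. Elovl6 was at -0.36.

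Lysosome and autophagy genes were higher in 28 of 29 members with a median of 0.16 (camera on the edgeR fit, adjusted p = 4.4e-10), with adjusted p = 0.168 with an estimated correlation. Ctsa and Grn were at 0.27 and 0.25, and no member passed among all genes with the block, 6 passed adjusted over the list alone and 0 without the block. Ribosomal protein genes were positive in 53 of 56 members (median 0.10, adjusted p = 6.5e-07 by camera and edgeR), with adjusted p = 0.577 with an estimated correlation and a difference of -0.21 in pair 4. The call ended without LG replicate 1 (0.0559), and without the preparation of numbers 1 and 2 the sign turned (0.593), by camera on the edgeR fit. Many of these genes have pseudogene copies, so their counts are uncertain. The share of counts in ribosomal protein genes was 3.24 ± 0.256% in HG and 3.48 ± 0.275% in LG (exact permutation p = 0.257).

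Other genes that changed with the block included Slfn9 (-0.82), Itga8 (-0.70), Esf1 (-0.67) and Inpp4b (-0.64), which fell, and Capn5 (0.51), Draxin (0.49), Mif4gd (0.47) and Tmem132b (0.47), which rose. Of the 21 genes named here that passed with the replicate block, 1 passed with the preparation block (Itga8, edgeR adjusted p = 0.0320) and 10 with blocked sums per preparation: Mki67, Cenpe, Knl1, Clspn, Neu4, Myrf, Slfn9, Itga8, Esf1 and Tmem132b. Over the 25 settings Slfn9 ran from -1.27 to -0.35, Esf1 from -0.92 to -0.30, Cenpe from -1.08 to -0.43, Kif20b from -0.95 to -0.33, Knl1 from -0.88 to -0.43, Dtl from -0.58 to -0.27 and Fa2h from 0.27 to 0.77. Fold changes followed GC content across genes, at a rank correlation of 0.525 with the block and -0.04 with the offsets as well. Genes are not independent replicates. The rank correlation of a single library with GC ran from -0.56 to 0.43 in HG and from -0.08 to 0.41 in LG, and the group means did not differ by the exact permutation test (p = 0.314).

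Markers of other cell types were measured beside the progenitor genes. Astrocyte markers did not pass without the block (adjusted p = 0.477 by camera on the edgeR fit) and passed upward with it (adjusted p = 0.00431), with adjusted p = 0.641 with an estimated correlation. Their median difference was 0.13 ± 0.17 (SD over 4 pairs). Their score lay at 1.05 to 1.29 in libraries 1 and 2 of both groups and at -1.35 to -0.88 in libraries 3 and 4, the parting seen along the first principal component. Neuron markers were at 0.02 ± 0.06 and did not pass in either fit. Endothelial markers were higher in LG in 4 of 4 pairs (0.23 ± 0.08) and in all 4 tested members, and did not pass as a list (adjusted p = 0.338 by camera on the edgeR fit without the block and 0.216 with it). The most abundant marker of each type was neuronal Map2 at 874 CPM, astrocytic Slc1a3 at 436 CPM, fibroblast Fbln1 at 34.5 CPM, mural Notch3 at 24.1 CPM, endothelial Vwf at 3.57 CPM and microglial Cd68 at 1.20 CPM, against 1766 CPM for Pdgfra. The second most abundant were, in the same order, Gap43 at 198 CPM, Sox9 at 279, Ogn at 0.305, Pdgfrb at 2.40, Kdr at 2.30 and Laptm5 at 1.16. Only 3 of 12 fibroblast and 7 of 12 mural members were tested. A single abundant member therefore does not show that a cell type was present. The 10 most abundant genes took 9.89 ± 0.806% of counts in HG and 8.85 ± 1.15% in LG (SD, n = 4, exact permutation p = 0.2). This share was higher in LG in 0 of 4 pairs, and the permutation test does not use the pairing.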

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

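The offsets in the list test, the test of progenitor identity genes, both tests of the GC trend and the count of splits for the fit with offsets were chosen after their results were seen, while the other tests in this part were chosen before their results were seen. In 210 groups of 4 libraries, 11 had 1 library far from the other 3, against 10.5 that chance gives at 1 in 20. Within its own group of 4 libraries, Ccna2 was lowest in HG replicate 3 at 7.49 log2 CPM, Ccnd1 in HG replicate 2 at 9.12, Sirt2 in LG replicate 2 at 8.07, Gria3 in HG replicate 2 at 6.92 and Pdk2 in HG replicate 1 at 4.75. Within these groups the premyelinating list score was lowest in HG replicate 3 at -0.44 and highest in LG replicate 4 at 0.37. Likewise within a group, the G2/M score was highest in HG replicate 1 at 0.32, the histone deacetylase score lowest there at -0.16, the score of endoplasmic reticulum genes highest in HG replicate 4 at 0.060 and that of ribosome biogenesis highest in LG replicate 1 at 0.067.

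Cell cycle genes were lower in LG in 4 of 4 pairs. With GC and length offsets the mean pair difference of the 80 members was -0.21 ± 0.07, against -0.22 ± 0.04 without them. Lists matched on GC content, length and expression had a median log2 fold change of 0.016 with the block, against -0.23 for the members. Both values argue against GC and length bias as the whole cause. Of 10000 matched lists 0 were as low, but these hold genes drawn singly, so that count does not measure variation over libraries. A higher share in LG of cells that lack progenitor identity genes would lower these genes alike. They lay above the cell cycle genes by 0.23 ± 0.05 (mean ± SD) in 4 of 4 pairs, so as a list they did not fall with them. This argues against such cells as the whole cause only if the identity genes did not change for other reasons. With the block 15 were positive and 10 negative, and 3 passed as higher and 1 as lower adjusted over the list alone. A rise of some members could therefore mask such a fall. Endothelial markers were nonetheless higher in 4 of 4 pairs (0.23 ± 0.08), and astrocyte markers passed upward with the block (adjusted p = 0.00431 by camera on the edgeR fit, adjusted p = 0.641 with an estimated correlation). The comparison cannot weigh a higher share of cells that express the identity genes. Premyelinating markers were higher in LG in 15 of 16 members, and a higher share of such cells was not tested. Chance could not be excluded without the pairing: 4 of the 35 splits of the libraries gave a difference in the mean score as large as the real 0.244, the highest 0.300, and 1 of these parted numbers 1 and 2, which share a preparation, from 3 and 4. Among the 8 splits that part all pairs the real one was the largest (highest other 0.134), but 8 are too few for a share under 0.05, so an effect of glucose on the cell cycle may be one candidate explanation and stays a hypothesis.

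Fold changes that followed GC content fit a bias of single libraries: the GC rank correlation ranged by 0.982 within HG, against a difference of 0.291 between the groups. Glucose itself may also be involved, since the correlation was higher in LG in 3 of 4 pairs, but 11 of 35 splits gave a difference as large (highest 0.542) and pair 4 went the other way by 0.198 (LG minus HG -0.198), within the spread of the pairs, so these cannot be told apart.

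The mitochondrial genes at 0 stand beside 7 pseudogenes on GRCm38 chromosome 1, from 24611535 (start of Gm28439) to 24616197 (end of Gm29216), that match mitochondrial transcripts and hold 94.0% of the counts of unprocessed pseudogenes. Mitochondrial reads counted on these nuclear copies may be the source, and no biological explanation was tested.

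Without a block the real split gave 0 genes, so 35 of 35 splits reached that count, and the highest other gave 3305. This split parted numbers 1 and 2, which share a preparation, from 3 and 4, which have a preparation code each. It points to a difference of the preparation of numbers 1 and 2 from the others, not to a grouping of every library by preparation. For lists, 2 of the 35 splits gave as many as the real 12, the highest other also 12, so chance was not excluded. With the block, 8 splits part all pairs, too few for a share under 0.05: the real one gave 79 genes and the highest other 0, the real one gave 17 lists and the highest other 9, and with the offsets the real one gave 293 genes and the highest other 1. In each of these 3 counts 1 of the 8 splits, the real one, was as large.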

How the results depend on the processing

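The alternatives to the fits with the replicate block, the list test with offsets and 4 library measures (nuclear mitochondrial copies, the most abundant gene ID, GC and length trends) were chosen after seeing the data. Causes of the shifts were not tested. Without a block, 0 genes passed under the other filters, RLE, thinning, limma-voom, GC and length offsets and each left-out library or preparation. Stricter thresholds also gave 0, but they could not add calls to a fit that had 0. The count was 79 with the replicate block, 1 with the preparation block, 4 by DESeq2, 441 by DESeq2 with the replicate block, 17 with counts summed per preparation and blocked, and 293 with GC and length offsets and the replicate block. Starting from the 79, it was 739 with no filter, 1 with the preparation block, 5 at an adjusted p under 0.01, 0 by glmTreat at 1.5-fold, 441 by DESeq2 and 293 with offsets, and 0 to 148 without 1 pair. Starting from the 293, it was 51 at an adjusted p under 0.01 and 38 (without pair 2) to 517 (without pair 4) without 1 pair. RLE moves nothing there, since the offsets replace the scaling. List calls, 12 without and 17 with the block, fell to 7 without the preparation of numbers 1 and 2, 0 with an estimated correlation in each fit and 0 by fry, or 3 by fry with the replicate block; 0 passed by either with the offsets. Leaving out 1 library gave 8 to 16 lists. The lowest r of the pairing was 0.703 at a mean CPM of at least 10. No library measure passed under any alternative by the permutation test, which does not use the pairing. The sign turned for the nuclear mitochondrial copies without HG replicate 4 (exact permutation p = 0.943) and without LG replicate 2 (p = 0.686, range 0.371 to 1).

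The sign of genes and lists that had not passed, or of list calls that were lost, turned as follows. Without the preparation of numbers 1 and 2, ribosomal proteins had adjusted p = 0.593 (camera on the edgeR fit), and the log2 fold changes were -0.024 for Gapdh, -0.038 for Cspg4 and -0.086 for Slc2a1. Astrocyte markers turned without HG replicate 3 (adjusted p = 0.750), HG replicate 4 (0.717), LG replicate 1 (0.534) and LG replicate 2 (0.755), by camera on the edgeR fit, with a lowest adjusted p of 0.00847 without LG replicate 4. Acly was at 0.0023 with the replicate block, 0.0021 with the preparation block, 0.0057 with RLE, 0.0034 with no filter, 0.0090 by DESeq2, 0.013 by DESeq2 with the replicate block, 0.0023 by limma-voom, 0.0039 with sums per preparation and 0.0084 with blocked sums. It was at 0.043 without the preparation of number 4 and from -0.055 (without LG replicate 4) to 0.098 (without HG replicate 4). Acss2 ran from -0.0031 without LG replicate 1 to 0.059 without LG replicate 4. Cspg4 ran from -0.10 to 0.17 without 1 library, and was at -0.0045 with offsets. Mbp ran from -0.27 to 0.36 without 1 library, and was at -0.067 and -0.013 without the preparations of numbers 3 and 4, and -0.012 with offsets. Slc2a1 ran from -0.057 to 0.11 without 1 library, and was at -0.0067 with blocked sums, -0.040 with offsets and -0.045 with offsets and the replicate block. With the sign kept, these log2 fold changes moved by over 1.5 times from the value with the block over the 25 settings: Pdgfra -0.20 to -0.0057, Vcan -0.24 to -0.064, Gria3 -0.50 to -0.22, Egr1 -0.42 to -0.16, Klf10 -0.41 to -0.21, Txnip -0.55 to -0.27, Elovl6 -0.47 to -0.16, Irs2 0.15 to 0.44, Pmaip1 -0.44 to -0.19, Mdm2 -0.33 to -0.13, Grn 0.14 to 0.32, Pfkm 0.099 to 0.27 and Hk1 0.035 to 0.17.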

Other observations

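The most abundant gene ID, ENSMUSG00000119584, had no symbol in the annotation used here. It took 6.38 ± 0.705% of the counts in HG and 5.18 ± 1.33% in LG (SD, n = 4, exact permutation p = 0.171), and was lower in LG in 4 of 4 pairs. The FOXO and insulin signalling list was positive in 12 of 16 members with the block (adjusted p = 0.0263 by camera on the edgeR fit, adjusted p = 0.601 with an estimated correlation; 0.0557 without the block), where Irs2, an insulin receptor substrate gene, was at 0.32 and Pdk2, which inhibits pyruvate dehydrogenase, at 0.28. The ribosome biogenesis list was negative in 16 of 25 members with the block (adjusted p = 0.0263 by camera on the edgeR fit, adjusted p = 0.641 with an estimated correlation), and did not pass without the block (0.245) or with the preparation block (0.119). Cholesterol synthesis genes were negative in 20 of 25 members with the block and the offsets (adjusted p = 0.0288 by camera on the edgeR fit, adjusted p = 0.786 with an estimated correlation), and in 18 of 25 without the offsets, where the list did not pass (adjusted p = 0.202). The amino acid response list did not pass in either fit, and its member Slc7a1, a cationic amino acid transporter gene, was at -0.24 with the block.

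Total counts of 50864130 to 65733928 per library lie above the read depth that the protocol states, and how the deposited counts relate to read pairs is open.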
